A study of Mus musculus with 8 samples.

How the data were processed

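Gene expression was measured by RNA sequencing in N2a cells, a mouse neuroblastoma line, in 8 libraries: 4 from control cells and 4 from cells collected 24 hours after transient transfection with an Nrsn2 overexpression construct. Per the labels' protocols, total RNA was isolated with a spin-column kit, and polyA libraries were made with a TruSeq V2 kit, which does not mark strand, and sequenced as single-end reads. The control libraries carry the same time of 24 hours after transfection as the overexpression libraries. The labels do not say what the control cells received, and no mock or empty-vector treatment is named. They also do not say whether the replicates of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

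One table covering all samples was used. The submitters' processing notes name cutadapt 2.10, TopHat2 2.1.1, HTSeq 2.01, DESeq2 1.36.0 and the genome build GRCm39. The role of each tool, the annotation release and the strand setting of the counting are not given in the sources used here. Per the file headers, the deposited counts are whole-number read counts per Ensembl gene for each sample. Per the file headers, a second set of columns holds the same counts divided by DESeq2 size factors, a normalized signal made by the authors, with its mean over all samples. The authors' own comparison of overexpression with control is given as a log2 fold change with its standard error, per the file headers. It also holds the authors' Wald statistic, a score, and the authors' p-value and adjusted p-value for each gene. The authors marked genes as significant where the adjusted p-value was under 0.1, and tested genes with at least 10 counts over all samples. Of 55414 rows, 6250 had no value in any sample and were left out, and 49164 had counts. No row lacked a gene name, and no column belonged to a sample outside the series. Gene positions are those of the deposited table on GRCm39. The mouse reference available here was an older build, so it was used only by gene identifier for transcript length and GC content, and 99.8% of the tested genes had a match.

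Library totals ranged from 15347255 to 21395096 counts. The groups were compared on the deposited counts with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3), TMM normalization, no covariate and no fold threshold. Genes were filtered with filterByExpr at a minimum count of 10, which left 15187 genes. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. Standard errors of log2 fold changes were derived from the F statistic. Levels are CPM, counts scaled by edgeR to a common library total with TMM factors, given as mean ± SD over the 4 libraries of a group. The common biological coefficient of variation was 0.0862. Single measures of libraries were compared by two-sided exact permutation tests over the 70 arrangements of the 8 libraries, whose smallest possible p is 0.0286. The comparison was tested on simulated data made from the real means and library sizes over 14962 genes. In these data 200 genes were changed by 1.5-fold or 2-fold, and all genes had the same biological coefficient of variation, the common one. The comparison called 76% of genes changed by 1.5-fold and 88% of genes changed by 2-fold, and 5.38% of its calls were unchanged genes. Far more genes were called in the real data, so these shares need not hold there.

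A set of 26 gene lists with 626 distinct symbols was fixed before the data were examined. Lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists. Members were counted after adjustment over all tested genes and again adjusted over the list alone. In the simulated data, camera called a list shifted by 1.3-fold and 0 of 20 unchanged lists. The simulated genes varied independently, so this does not test false calls of lists whose members vary together. Named genes followed a rule fixed at the same time. It took Nrsn2, then the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 CPM and no overlap between the groups. Predicted genes, clone names and pseudogenes were skipped. From every list it took the 4 tested members with the smallest p. It named 120 genes, not all of which are given in the text. Of these, 39 overlap another counted gene, and with a kit that does not mark strand, reads of overlapping genes cannot be told apart. None of the other named genes compared shared a 31-base sequence with Nrsn2 transcripts, and the 7SK copy, whose identifier had no match in the reference, was not compared. Genes outside the rule that were chosen after their values were seen are marked as such. The transcripts chosen as nuclear and the targets of the sterol sensor LXR were fixed before their results. Gm14164 is named because it overlaps Nrsn2.

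Alternatives fixed before the data were examined were other normalizations (DESeq2's median-of-ratios factors, upper-quartile factors, library totals alone, Nrsn2 left out), no low-count filter or a minimum count of 50, DESeq2 1.42.0, limma-voom, each library left out in turn, the replicate number as a block, other thresholds, and camera with an estimated correlation, camera on ranks and fry. Added later were offsets for GC content and transcript length, library totals without mitochondrially encoded genes, and a threshold of 0.1. Terms of the Gene Ontology given in the deposited table were tested with a hypergeometric test (scipy 1.17.1, adjusted with statsmodels 0.14.6) over the 12616 tested genes with a term, for 2097 terms of 15 to 500 genes in each direction. Figures were drawn with matplotlib 3.10.9.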

Results

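N2a cells, a line derived from a mouse neuroblastoma, were used to ask which transcripts change when the stress-responsive protein neurensin-2 is overexpressed. Nrsn2 encodes this small membrane protein of neuronal vesicles. PolyA RNA was sequenced from 4 control libraries and from 4 libraries of cells collected 24 hours after transfection with the Nrsn2 construct. Control libraries 1 to 4 held 17413411, 17371352, 15347255 and 20600086 counts, and overexpression libraries 1 to 4 held 17522453, 21395096, 19273114 and 18252251 counts (two-sided exact permutation p of the difference between groups = 0.343). Replicates within a group differed by more than counting noise in every pair, with a chi-square per degree of freedom of 2.59 to 15.6, so no library was treated as a duplicate. The first principal component held 50.2% of the variance and separated the groups.

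Nrsn2 (ENSMUSG00000059361; GRCm39 chromosome 2, 152210675 to 152218558, minus strand) was higher in every overexpression library than in every control library. The control libraries 1 to 4 held 8.42, 8.53, 6.54 and 10.6 CPM. The overexpression libraries 1 to 4 held 147, 173, 156 and 170 CPM. The group means were 8.53 ± 1.67 and 161 ± 12 CPM (SD, n = 4 each), a log2 fold change of 4.23 ± 0.11 (SE; edgeR adjusted p = 2.89e-15; two-sided exact permutation p of the CPM values = 0.0286, the smallest the design allows). The gene overlaps the annotated antisense transcript Gm14164, which held 3 to 21 counts per library, and reads from both cannot be told apart without strand. In the authors' deposited table the log2 fold change of Nrsn2 was 4.22 with a standard error of 0.11.

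Overexpression of Nrsn2 was accompanied by changes in 5369 of 15187 tested genes (35.4%), of which 2823 were higher and 2546 lower. Most changes were small, with a median absolute log2 fold change of 0.43, and 606 genes also changed by more than 2-fold (394 higher, 212 lower). Among the 12 named genes with the largest rises were the interferon-induced genes Isg15, Ifit1, Gbp3, Gbp7 and Samd9l. Isg15, a ubiquitin-like modifier (chromosome 4, 156283912 to 156285253), rose from 1.25 ± 0.62 to 8.76 ± 1.69 CPM (log2 fold change 2.75 ± 0.23; edgeR adjusted p = 2.02e-07). Unc13d, which encodes a vesicle-priming protein of regulated secretion (chromosome 11, 115952921 to 115968787), rose from 5.67 ± 0.69 to 29.3 ± 5.76 CPM (log2 fold change 2.36 ± 0.13). Cfap53, a gene of cilia and flagella, had a log2 fold change of 3.89 ± 0.33, and Pygm, the muscle form of glycogen phosphorylase, one of 3.16 ± 0.26, both from under 1 CPM in the control group. Also among the largest rises were the long noncoding RNA BC051077 (2.73 ± 0.20), the membrane adaptor gene Pag1 (2.52 ± 0.32), Evpl (2.47 ± 0.39) and Hgd, an enzyme of tyrosine breakdown (2.42 ± 0.27).

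**Figure D1:**
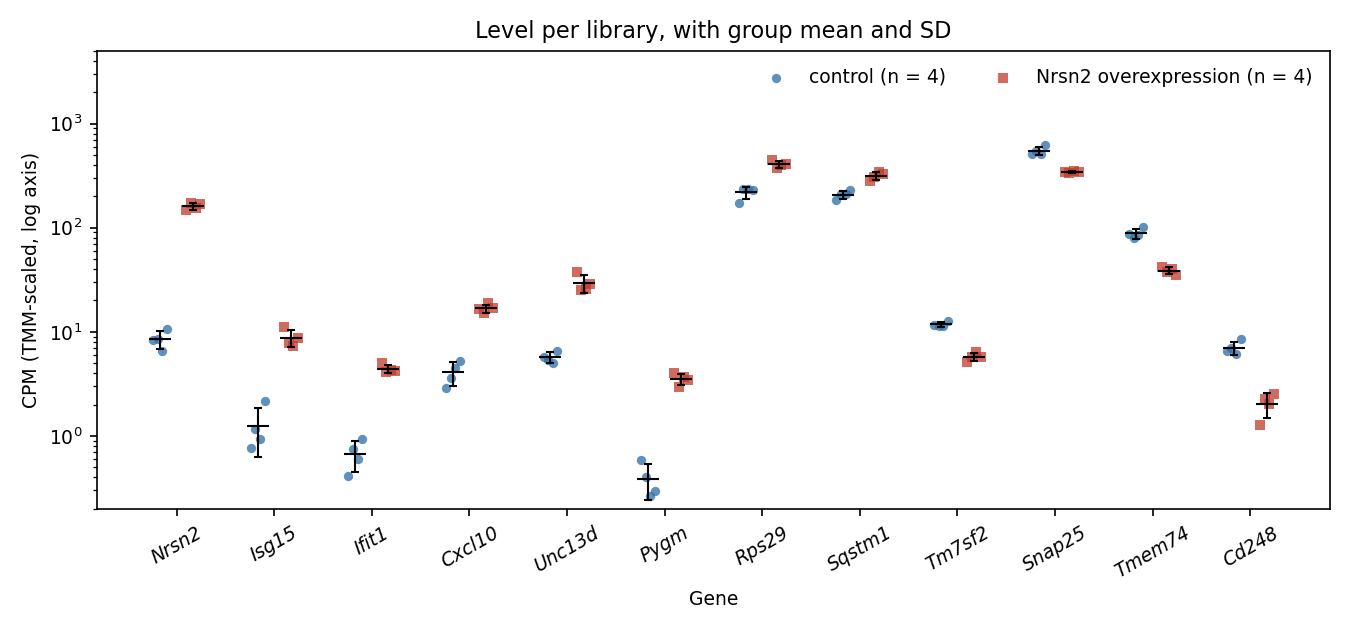
CPM per library on a log axis for 12 named genes, with circles for the 4 control and squares for the 4 Nrsn2 overexpression libraries, and black bars for the group mean and SD. The overexpression libraries lie above all control libraries for Nrsn2, from 147 to 173 CPM against 6.54 to 10.6 CPM, and below them for Cd248, with means of 2.03 and 6.98 CPM.

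The largest falls among the named genes were smaller than the largest rises. Cd248, which encodes the cell-surface glycoprotein endosialin (chromosome 19, 5118106 to 5120710), fell from 6.98 ± 1.05 to 2.03 ± 0.54 CPM (log2 fold change -1.78 ± 0.18; edgeR adjusted p = 1.82e-06). Among more abundant transcripts, Mblac2 (chromosome 13, 81859460 to 81901394) fell from 66.0 ± 6.15 to 26.7 ± 1.93 CPM, Tmem74 (chromosome 15, 43728042 to 43733432) from 88.2 ± 9.90 to 38.7 ± 2.85 CPM and Myadm (chromosome 7, 3337605 to 3348958) from 370 ± 66.9 to 162 ± 22.2 CPM. Their log2 fold changes were -1.31 ± 0.08, -1.19 ± 0.08 and -1.19 ± 0.11. The chemokine gene Ccl28 had a log2 fold change of -1.22 ± 0.23, the transcription factor gene Tfap2b one of -1.11 ± 0.15, and Ppp1r3d, a glycogen-targeting subunit of protein phosphatase, one of -1.35 ± 0.28. Echdc3 (-1.18 ± 0.25) and a copy of the small nuclear RNA 7SK (-1.51 ± 0.33) completed the falls that did not rest on a single library. Of these, Myadm, Echdc3 and the 7SK copy overlap another counted gene, whose reads cannot be told apart. The 7SK copy was also scarce, at 1.53 ± 0.36 CPM in the control and 0.53 ± 0.27 CPM in the overexpression libraries. For Aldoc, Kbtbd11 and Pdzd7 the size of the fall rested on control library 4: without it, the log2 fold changes moved from -1.33 to -0.71, from -1.26 to -0.81 and from -1.25 to -0.76, and Pdzd7 no longer passed (edgeR adjusted p = 0.0771).

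**Figure D2:**
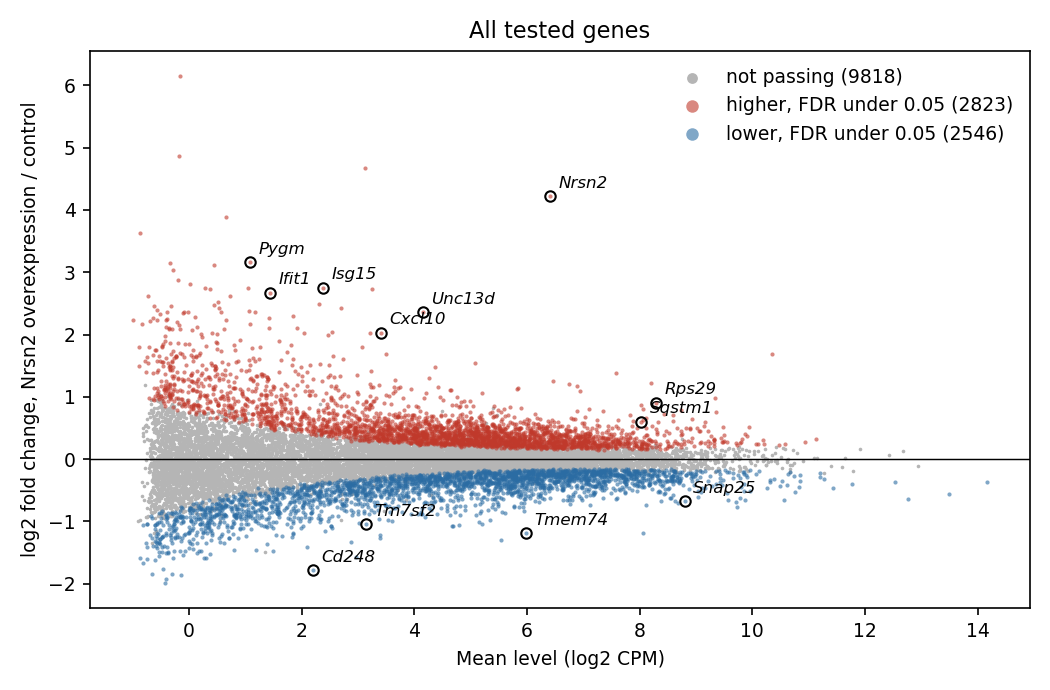
Log2 fold change (overexpression over control) against mean level (log2 CPM) for the 15187 tested genes, with the 2823 higher genes in red, the 2546 lower genes in blue and 12 named genes circled. Nrsn2 lies at a log2 fold change of 4.23, and the median absolute log2 fold change of the called genes is 0.43.

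Genes that respond to interferon were higher as a group. Of 25 tested members of this list, 19 were higher and 0 lower, also 19 when adjusted over the list alone, with a median log2 fold change of 1.36. Besides Isg15, the 4 members with the smallest p included Ifit1, an interferon-induced RNA-binding protein (log2 fold change 2.67 ± 0.22), Ifih1, a sensor of double-stranded RNA (2.36 ± 0.24), and the chemokine gene Cxcl10, which rose from 4.07 ± 1.04 to 16.8 ± 1.49 CPM (2.03 ± 0.14). The list was called by camera (adjusted p = 3.43e-10; adjusted p = 0.333 with an estimated correlation). Levels remained low, since Ifit1 reached 4.41 ± 0.41 CPM and Isg15 8.76 ± 1.69 CPM with overexpression. Gbp3, Gbp7 and Ifit1 belong to families with similar copies, so their values are uncertain where reads are shared.

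Genes of cholesterol synthesis fell together. Of 24 tested members, 18 were lower and 0 higher, and 18 were lower when adjusted over the list alone, with a median log2 fold change of -0.35 (camera adjusted p = 3.64e-08; adjusted p = 0.333 with an estimated correlation). Tm7sf2, a sterol reductase, fell from 11.8 ± 0.65 to 5.75 ± 0.51 CPM (log2 fold change -1.04 ± 0.11). Pmvk, a kinase of the mevalonate pathway, had a log2 fold change of -0.64 ± 0.08, Nsdhl, a sterol dehydrogenase, one of -0.60 ± 0.07, and Acat2 one of -0.49 ± 0.06.

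Transcripts of cytosolic ribosomal proteins were higher. Of 50 tested, 39 were higher and 0 lower (40 higher when adjusted over the list alone), with a median log2 fold change of 0.31 (camera adjusted p = 1.54e-10; adjusted p = 0.529 with an estimated correlation). Rps29 rose from 218 ± 29.3 to 407 ± 31.7 CPM (log2 fold change 0.90 ± 0.09), and Rps14, Rps21 and Rps2 had log2 fold changes of 0.87 ± 0.09, 0.80 ± 0.09 and 0.79 ± 0.06. Across the genes of this comparison, shorter transcripts tended to be higher, with a median log2 fold change of 0.16 in the shortest 10% of protein-coding genes. So did GC-rich ones, with medians of -0.10 in the 10% lowest in GC content and 0.11 in the 10% highest. With offsets for GC content and length, the ribosomal list's median was 0.24. Without offsets, its median lay above that of each of 10000 random lists matched on length, GC content and mean level, the highest of which was 0.20. The random lists were drawn gene by gene. They do not allow for ribosomal protein genes varying together, whose estimated correlation was 0.487. Reads of these genes can be split with their many processed pseudogenes, of which 87 were tested, 9 higher and 2 lower, with a median of 0.05.

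Genes of autophagy and the lysosome were more often higher than lower. Of 34 tested members, 17 were higher and 2 lower (17 and 3 when adjusted over the list alone), with a median log2 fold change of 0.22 (camera adjusted p = 8.12e-04; adjusted p = 0.484 with an estimated correlation). Atg14, a subunit of the lipid kinase complex that starts autophagosomes, rose from 9.23 ± 0.58 to 18.3 ± 1.64 CPM (log2 fold change 0.99 ± 0.10). The autophagy receptor gene Sqstm1 (0.60 ± 0.08), Gabarap (0.59 ± 0.07), a protein of the autophagosome membrane, and the lysosomal membrane gene Lamp1 (0.44 ± 0.06) also rose. The 2 lower members, named after their values were seen, were the proton pump subunit Atp6v1a (-0.19 ± 0.06) and the lysosomal prosaposin gene Psap (-0.19 ± 0.07). Only 1 member was lower without control library 2 or 4 or overexpression library 2 or 3, and 0 without overexpression library 4.

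In both lists of neuronal genes that passed, more members were lower than higher. In the list of synaptic vesicle and exocytosis genes, 11 of 23 tested members were lower and 0 higher (11 lower and 2 higher when adjusted over the list alone), with a median log2 fold change of -0.20 (camera adjusted p = 0.00773; adjusted p = 0.529 with an estimated correlation). Snap25, a component of the synaptic fusion complex, fell from 547 ± 52.4 to 342 ± 8.48 CPM (log2 fold change -0.68 ± 0.07), and Cplx2, Syn1 and Napb had log2 fold changes of -0.72 ± 0.07, -0.54 ± 0.09 and -0.50 ± 0.07. In the list of neuronal differentiation and neurites, 12 of 25 tested members were lower and 2 higher (13 and 2 when adjusted over the list alone), with a median of -0.26 (camera adjusted p = 0.00266; adjusted p = 0.484 with an estimated correlation). The growth-associated gene Gap43 (-0.57 ± 0.08), the adhesion gene L1cam (-0.55 ± 0.08), the transcription factor gene Isl1 (-0.51 ± 0.08) and the microtubule regulator gene Stmn2 (-0.49 ± 0.06) were lower. The 2 higher members, named after their values were seen, were Uchl1 (0.34 ± 0.08) and Stmn3 (0.29 ± 0.10), and 1 member was higher without control library 1 or overexpression library 4. For synaptic vesicle genes, 1 member was higher without control library 3 or overexpression library 3. Among glutamate receptor and postsynaptic genes, 7 of 21 were lower and 2 higher, with the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.141), although it passed downward on the DESeq2 statistics (adjusted p = 0.0203, in a range of 0.0203 to 0.243 over the settings of camera with the preset correlation). Gria2, a subunit of the AMPA receptor, had a log2 fold change of -0.72 ± 0.08, Dlg3 one of -0.74 ± 0.13, Nsg2 one of -0.63 ± 0.08 and Homer1 one of -0.54 ± 0.07. In this list 1 member was higher without control library 1 or 3 or overexpression library 1 or 4.

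Transcripts of the mitochondrial genome took a smaller share of the counts with overexpression, 3.85 ± 0.56% against 5.22 ± 0.40% (SD, n = 4 each; two-sided exact permutation p = 0.0286, the smallest the design allows). Of 13 tested, 9 were lower and 0 higher (10 lower when adjusted over the list alone), with a median log2 fold change of -0.56 (camera adjusted p = 0.00106; adjusted p = 0.585 with an estimated correlation). mt-Nd5, mt-Cytb and mt-Nd4 had log2 fold changes of -0.64 ± 0.11, -0.56 ± 0.09 and -0.47 ± 0.09, and mt-Nd2 one of -0.66 ± 0.14. Overexpression library 1 stood apart, with a mean of 8.23 log2 CPM over the list, within the 8.09 to 8.53 of the control libraries, against 7.50 to 7.69 in the other overexpression libraries. Its mt-Nd2 level of 1669 CPM exceeded the 1595 CPM of control library 2, while mt-Nd5, mt-Cytb and mt-Nd4 were lower in all 4 overexpression libraries than in any control library. With offsets for GC content and length, 7 members were lower and the list's median was -0.36. Several of these genes have copies in the nuclear genome, so reads can be lost or split. Nuclear genes of oxidative phosphorylation did not move with them: 13 of 34 were higher and 4 lower (13 and 5 when adjusted over the list alone), with Ndufb8, Cox4i1 and Cox5b higher (0.54 ± 0.09, 0.49 ± 0.08 and 0.48 ± 0.08) and Cyc1 lower (-0.41 ± 0.06). That list did not pass (camera adjusted p = 0.116), though it passed upward without control library 2 (adjusted p = 0.0368), control library 3 (0.0360) or overexpression library 2 (0.0414), and also with limma-voom (0.0462) or no low-count filter (0.0441). Over all settings of camera with the preset correlation, its adjusted p ran from 0.0360 to 0.303.

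Genes of hypoxia and glycolysis were lower, with 18 of 27 tested members lower and 0 higher (20 lower when adjusted over the list alone) and a median log2 fold change of -0.41 (camera adjusted p = 0.00228; adjusted p = 0.705 with an estimated correlation, and 0.173 by fry). Pfkp, Pgam1 and Ldha, enzymes of glycolysis, had log2 fold changes of -0.57 ± 0.09, -0.45 ± 0.08 and -0.41 ± 0.08. Control library 4 held the highest levels of several members, with 20.6 CPM of Aldoc against 5.06 to 8.71 CPM in the other control libraries. Without it, 13 members were lower and 1 higher, and the median was -0.26 (camera adjusted p = 0.00784).

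**Figure D3:**
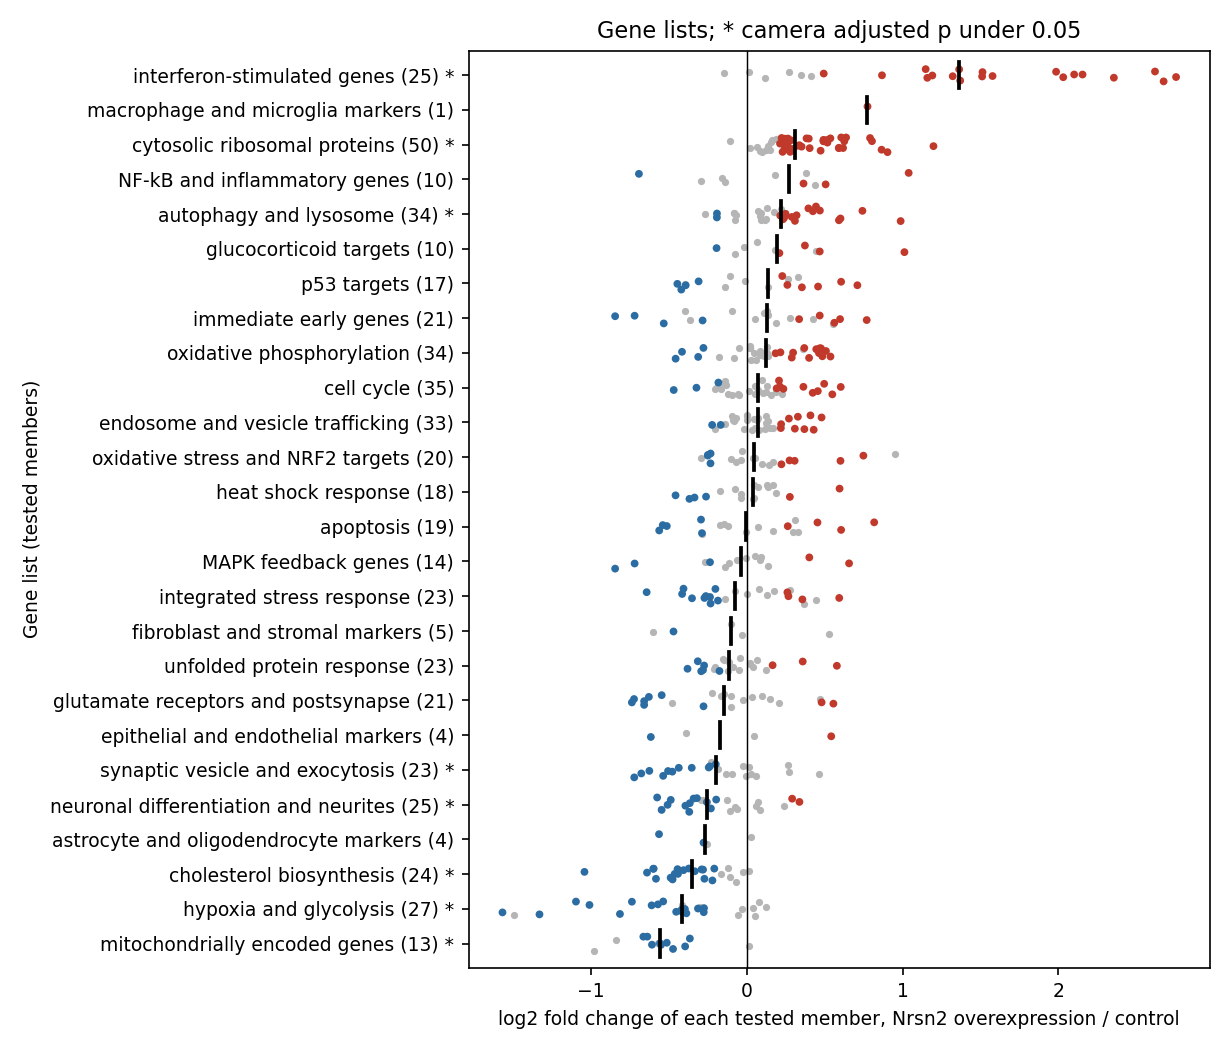
Log2 fold change (overexpression over control) of each tested member of the 26 gene lists, ordered by median, with red for members called higher, blue for members called lower, grey for the rest, black bars for medians and an asterisk for lists called by camera with the preset correlation. Medians run from 1.36 for interferon-stimulated genes to -0.56 for mitochondrially encoded genes.

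Stress and signalling lists did not pass as groups by camera, although single members changed. The integrated stress response had 4 of 23 members higher and 10 lower (5 and 10 when adjusted over the list alone; camera adjusted p = 0.288), and the lower ones included the amino acid synthesis genes Psat1 (-0.40 ± 0.06), Cth (-0.64 ± 0.12) and Psph (-0.35 ± 0.07) and the glutathione-degrading enzyme gene Chac1 (-0.41 ± 0.09). Without control library 1 or 3, 2 of its members were higher. The unfolded protein response had 3 of 23 higher and 6 lower (3 and 6 when adjusted over the list alone; adjusted p = 0.233). The transcription factor gene Ddit3 was higher (0.58 ± 0.11), while Xbp1 (-0.29 ± 0.07), Pdia6 (-0.28 ± 0.06) and Pdia4 (-0.27 ± 0.07) were lower. In the heat shock list, 2 of 18 were higher and 4 lower (2 and 4 when adjusted over the list alone; adjusted p = 0.985, with a test direction opposite in sign to the median of 0.04). The co-chaperone gene Bag3 was higher (0.60 ± 0.07), and Hsp90aa1 (-0.46 ± 0.08), Hspa4 (-0.37 ± 0.08) and Stip1 (-0.33 ± 0.07) were lower, and 5 members were higher without overexpression library 1. Among NRF2 targets, 5 of 20 were higher and 4 lower (5 and 4 when adjusted over the list alone; adjusted p = 0.595), with the ferritin genes Ftl1 (0.75 ± 0.08) and Fth1 (0.31 ± 0.07) and the thioredoxin gene Txn1 (0.28 ± 0.07) among the higher. Among p53 targets, 6 of 17 were higher and 4 lower (7 and 4 when adjusted over the list alone; adjusted p = 0.550). Gtse1 (0.71 ± 0.08), Bax (0.61 ± 0.09) and Mdm2 (0.35 ± 0.06) were higher and Ccng1 (-0.42 ± 0.07) lower.

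In the apoptosis list, 4 of 19 members were higher and 5 lower, with the same counts adjusted over the list alone (adjusted p = 0.655), and the list's mean of 0.02 was opposite in sign to its median of -0.002 and its test. The death effector genes Bak1 (0.82 ± 0.14) and Bax were higher, and the survival genes Bcl2 (-0.56 ± 0.11) and Xiap (-0.54 ± 0.08) lower. Among cell cycle genes, 10 of 35 were higher and 3 lower (11 and 4 when adjusted over the list alone; adjusted p = 0.285). The mitotic genes Kif20a (0.55 ± 0.08), Plk1 (0.50 ± 0.07) and Aurka (0.42 ± 0.07) were higher and Top2a (-0.47 ± 0.07) lower, and 6 members were lower without control library 4. Of immediate early genes, 5 of 21 were higher and 4 lower (6 and 4 when adjusted over the list alone; adjusted p = 0.478), with Egr1 (-0.72 ± 0.14) and Nr4a3 (-0.53 ± 0.11) lower and Nr4a1 (0.60 ± 0.14) and Klf4 (0.34 ± 0.09) higher. Without control library 1 or 2 or overexpression library 4, 3 immediate early genes were higher. MAPK feedback genes had 2 of 14 higher and 3 lower, with the same counts adjusted over the list alone (adjusted p = 0.632), with Dusp4 higher (0.40 ± 0.10) and Egr1, Ier3 (-0.84 ± 0.23) and Spry4 (-0.23 ± 0.08) lower. Without control library 4, the log2 fold change of Ier3 was -0.44 and Spry4 no longer passed (edgeR adjusted p = 0.0581), nor did Spry4 without overexpression library 3 (0.0852). Ier3 did not pass with DESeq2 (DESeq2 adjusted p = 0.0676), nor Spry4 by library totals alone (edgeR adjusted p = 0.0527). The count of higher MAPK feedback genes was 1 without control library 1 or 2 or overexpression library 1. NF-kB and inflammatory genes had 3 of 10 higher and 1 lower, again unchanged when adjusted over the list alone (adjusted p = 0.457), with Tnfaip3 (1.04 ± 0.22) and Nfkb1 (0.36 ± 0.09) higher and Birc3 (-0.69 ± 0.17) lower. Glucocorticoid targets had 4 of 10 higher and 1 lower, the same when adjusted over the list alone (adjusted p = 0.248), with the clock gene Per1 (1.01 ± 0.15) and the kinase gene Sgk1 (0.37 ± 0.09) higher. The higher count of this list was 2 without control library 2 or 3 or overexpression library 4, and the lower count 0 without control library 2 or overexpression library 2, 3 or 4. Endosome and vesicle trafficking genes, the group closest to the known location of neurensins, had 9 of 33 higher and 2 lower (8 and 2 when adjusted over the list alone; adjusted p = 0.150). Rab35 (0.48 ± 0.09), the clathrin light chain gene Clta (0.43 ± 0.07), Vps4a (0.37 ± 0.07) and Ap3d1 (0.31 ± 0.07) were higher. The lower count was 1 without control library 1, 3 or 4 or overexpression library 3 or 4, and 0 without overexpression library 2.

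Markers of other cell types were rarely above the filter. Of 13 macrophage and microglia markers, Cd68 was the one tested, at 0.79 ± 0.13 and 1.34 ± 0.30 CPM (log2 fold change 0.77 ± 0.26; edgeR adjusted p = 0.0275; camera adjusted p = 0.282). Of 5 fibroblast and stromal markers tested, Acta2 was lower (-0.48 ± 0.13) and 0 were higher (camera adjusted p = 0.550). Of 4 astrocyte and oligodendrocyte markers, 2 were lower, Cnp (-0.56 ± 0.13) and Mbp (-0.28 ± 0.11), and 0 higher (camera adjusted p = 0.248). Of 4 epithelial and endothelial markers, Vwf was lower (-0.61 ± 0.16) and Tek higher (0.54 ± 0.20; camera adjusted p = 0.695). These counts were the same when adjusted over the list alone. The calls of Cd68, Mbp and Tek were weak: Cd68 no longer passed without control library 1, 3 or 4 or overexpression library 1 or 2 (edgeR adjusted p of 0.0568 to 0.0957). Mbp no longer passed without control library 1, 2 or 4 or overexpression library 1, 3 or 4 (0.0631 to 0.149), nor Tek without control library 2, 3 or 4 or overexpression library 2 or 3 (0.0592 to 0.134). In all, 8 of the 26 lists passed with the preset correlation, 3 upward and 5 downward, and 0 passed with an estimated correlation.

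In the authors' deposited table, 23163 genes were tested and 4825 had an adjusted p under 0.05, 2523 of them higher and 2302 lower with overexpression. The authors' deposited table marked 5923 genes at their threshold of 0.1. Of the 15186 genes with an adjusted p in both, 4599 were called at 0.05 in the authors' deposited table and in the edgeR fit, all with the same sign. Among these 15186 genes, a further 769 were called by edgeR only, and 9 in the authors' deposited table only. Genes called by the authors but removed by the low-count filter used here are not in that count.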

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

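The test of an introduced construct or reagent was chosen after the result was seen. The other tests on the patterns weighed here were written before their results.

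Of 302 sets of 4 libraries examined (library measures, list scores and named genes in each group), 17 (5.63%) had 1 library far from the other 3, and about 1 in 20 sets is picked out this way by chance. Overexpression library 2 was the distant one in 6 sets and overexpression library 1 in 4. By mean log2 CPM, overexpression library 2 stood at 6.79 for NRF2 targets (others 6.74 to 6.75), at 6.70 for oxidative phosphorylation (6.80 to 6.82) and at 5.32 for synaptic vesicle genes (5.23 to 5.24), and control library 4 at 6.87 for cell cycle genes (7.03 to 7.06). By CPM, overexpression library 1 stood above the others of its group for Cfap53 (3.12 against 2.48 to 2.50), BC051077 (24.2 against 12.7 to 14.5), Gabarap (69.2 against 59.1 to 60.4) and Lamp1 (751 against 656 to 671). Overexpression library 2 stood below for Pag1 (1.55 against 2.39 to 2.45) and Mblac2 (23.8 against 27.5 to 27.7) and above for Bcl2 (9.74 against 8.47 to 8.53). Overexpression library 3 was low for Per1 (7.43 against 8.83 to 9.04), and overexpression library 4 was high for Acta2 (8.70 against 7.38 to 7.59). Control library 1 was low for Rps29 (174 against 230 to 234) and high for Kif20a (33.1 against 28.4 to 29.0), control library 2 was low for Pdia4 (173 against 186 to 188), and control library 4 was high for Tm7sf2 (12.8 against 11.4 to 11.6). Over all tested genes, overexpression library 1 was far from its group in 513 (3.38%), against 97 to 275 in each other library.

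Interferon-stimulated genes were higher with overexpression. Immune cells as the source of these transcripts are argued against. Together, 7 abundant macrophage transcripts rose by 0.445 CPM, from 0.414 ± 0.276 to 0.859 ± 0.293. The mean rise was 6.43 CPM per called interferon-stimulated gene. An effect of a few immune cells on the N2a cells was not tested, and the macrophage marker Cd68 was weakly called higher (0.77 ± 0.26). A trend with GC content and transcript length is argued against as the whole cause, since with offsets for it the list's median log2 fold change was 1.3, or 95.4% of the uncorrected one. Introduced DNA or transfection reagent stays open. The control samples also carry a time of 24 hours after transfection. However, 0 of them have a label naming a mock or empty-vector treatment, so an effect of transfection and an effect of Nrsn2 cannot be told apart. The same limit applies to every difference between these groups.

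Hypoxia and glycolysis genes were lower with overexpression, and control library 4 held the highest levels of several. That library as the whole cause is argued against, since without it 13 of the 18 called members were still called, although the median moved from -0.41 to -0.26. By mean log2 CPM over the list, control library 4 stood at 7.01 and control libraries 1, 2 and 3 at 6.02, 6.39 and 6.10, which overlaps the 5.81 to 6.08 of the overexpression libraries. A trend with GC content and length is argued against, since with offsets for it the median was -0.47 (camera adjusted p = 2.36e-04, within a range of 2.33e-05 to 0.00905 over the other settings of camera with the preset correlation). A difference in growth conditions between cultures was not tested.

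Transcripts annotated as to be experimentally verified (TEC), mostly overlapping tested protein-coding genes, were lower. Of 861 tested, 260 were lower and 65 higher, with a median log2 fold change of -0.38. The fall was seen in those overlapping a tested protein-coding gene on either strand, since 208 that overlap none had a median of -0.04. The TEC share of all counts did not differ detectably (0.674 ± 0.0185% and 0.672 ± 0.0235%, n = 4 each; two-sided exact permutation p = 0.886). A fall of the genes they overlap is argued against. The 646 that overlap a single tested protein-coding gene had a median of -0.50, while those genes had one of -0.0573. A trend with GC content and length is argued against as the whole cause, with a median of -0.27 under offsets for it. A lower share of nuclear RNA stays open: 8 transcripts chosen as nuclear, of which Nktr is protein-coding, had a median of -0.43 with a standard error of 0.23 (-0.46 for the 7 noncoding ones), Xist (-0.63 ± 0.08) and Kcnq1ot1 (-0.46 ± 0.08) among the lower, but Neat1 was higher (0.36 ± 0.11) and Malat1 did not pass (-0.01 ± 0.08). An effect of Nrsn2 itself is open and untested.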

How the results depend on the processing

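Offsets for GC content and length, totals without mitochondrial genes and the threshold of 0.1 were chosen after the data were seen.

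The log2 fold change of Nrsn2 stayed called in the same direction under all 19 alternatives that give it. Between 4539 (without overexpression library 3) and 5511 genes (without overexpression library 1) were called with 1 library left out, 4927 with DESeq2, 5358 with limma-voom and 5364 by library totals alone, where 60.7% were higher. With GC and length offsets 5465 were called, 4553 of them shared with the reported calls. With replicate numbers as a block (replicate block), 5097 were called and 4980 were shared, but the numbers do not pair the libraries. An adjusted p under 0.01 left 3328 genes (1815 higher, 1513 lower), and a 2-fold limit added to an adjusted p under 0.05 left 606 (394 higher, 212 lower), both by construction.

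With an estimated correlation 0 of the 8 called lists passed: adjusted p = 0.333 for interferon-stimulated and for cholesterol genes, 0.705 for hypoxia, 0.585 for mitochondrially encoded genes, 0.529 for ribosomal proteins and for synaptic vesicle genes, and 0.484 for autophagy and for neuronal differentiation. For these 8 lists the estimates ran from 0.0976 to 0.792, against the preset 0.01; the cause was not tested. Fry, which does not compare a list with other genes, called 13 lists, but not hypoxia (0.173). Upward, fry added endosome and vesicle trafficking (5.81e-04), macrophage and microglia markers (0.0241) and p53 targets (0.0346). Downward, it added glutamate receptors and postsynapse (0.0241), the unfolded protein response (0.0380) and apoptosis (0.0429). The heat shock list, never called, changed direction by library totals alone (0.939), with no filter (0.979), with the replicate block (0.975), with GC and length offsets (0.929), by fry (0.778) and without control library 1 (0.938) or 3 (0.883) or overexpression library 1 (0.733) or 2 (0.856). Over all single libraries left out, its adjusted p ran from 0.733 to 0.960, and the direction held in the other 4. The cause was not tested.

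Of the results counted for named genes other than Nrsn2, 2167 kept direction and side of the threshold, 55 lost their call and 3 reversed. The reversals were in genes that did not pass: without single libraries, the log2 fold change of Pecam1 ranged from -0.12 to 0.16 and of Aldh1l1 from -0.58 to 0.0359. In simulated data with 200 changed genes, 76% of genes changed by 1.5-fold were called, so changes of this size can be missed. The real comparison called 5369 genes, so the share missed in it can differ. How the share varies with count level or depth was not tested.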

Other observations

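The tests of Gene Ontology terms, of small nucleolar RNA hosts and of nonsense-mediated decay, and the exact permutation tests of list levels, were chosen after the differences between the groups had been seen.

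Among 2097 Gene Ontology terms, 91 held more higher genes than their share and 53 more lower genes at an adjusted p under 0.05 (hypergeometric test). The test treats genes as independent, so its p-values can be too small where the genes of a term vary together. Higher genes were frequent in cytoplasmic translation (55 of 82 genes, 16.5 by chance; adjusted p = 5.98e-17), mRNA processing (127 of 318, 63.8 by chance; adjusted p = 1.08e-13), rRNA processing (62 of 144, 28.9 by chance) and defense response to virus (44 of 129, 25.9 by chance; adjusted p = 0.00915). Lower genes were frequent in glutamatergic synapse (100 of 332, 54.8 by chance; adjusted p = 1.12e-07), cholesterol biosynthetic process (17 of 25, 4.13 by chance), peroxisome (40 of 104, 17.2 by chance; adjusted p = 1.44e-05) and basement membrane (23 of 61, 10.1 by chance; adjusted p = 0.00477).

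Outside the rule for named genes, and chosen after their values were seen, the ubiquitin gene Ubb rose from 176 ± 33.0 to 409 ± 7.60 CPM (log2 fold change 1.22 ± 0.10). Lars2, the mitochondrial leucyl-tRNA synthetase gene, rose from 613 ± 63.4 to 1982 ± 403 CPM (1.69 ± 0.11). The extracellular matrix gene Ncan (-1.04 ± 0.09) and the secretory granule gene Chgb (-0.77 ± 0.09) fell. Whether reads of these genes are shared with other genes was not examined.

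Transcripts that host small nucleolar RNAs were higher, with 10 of 13 tested higher and 0 lower and a median log2 fold change of 0.65 (camera p of the list = 3.60e-07, and 0.0575 with an estimated correlation, which does not pass), in a list put together after Snhg12 (1.25 ± 0.08), Snhg15 (1.13 ± 0.08) and Zfas1 (0.78 ± 0.08) had been seen. Many such transcripts are broken down by nonsense-mediated decay, so less of this decay may be a cause. The mRNAs of 7 factors of the pathway, which it also limits, were higher in 6 cases and lower in 0, among them Upf1 (0.51 ± 0.08) and Smg6 (0.56 ± 0.08; camera p of the list = 7.62e-04, and 0.0188 with an estimated correlation; two-sided exact permutation p of their mean level = 0.0286, the smallest the design allows). This test cannot decide the matter, because the Gene Ontology term for this decay (16 of 31 genes higher, 6.22 by chance) had been seen first, and other terms of RNA processing also held more higher genes than their share. Gas5, a well-known target, did not pass (0.04 ± 0.07).

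The fall of cholesterol synthesis genes may reflect more sterol sensed in the cell, in which case targets of the sterol sensor LXR would rise. The targets did not rise as a group against all other tested genes (limma camera p = 0.717, direction down; two-sided exact permutation p of their mean level per library = 0.0857). The direction is that of camera alone. Nr1h3 (1.09 ± 0.25), Apoe (0.78 ± 0.22) and Abca1 (0.31 ± 0.12) were higher. Scd2 (-0.42 ± 0.06), Lpcat3 (-0.30 ± 0.07) and Srebf1 (-0.22 ± 0.08) were lower. With 3 of the 8 targets higher, 3 lower and a median log2 fold change of 0.01, the test does not decide.

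Of the 35 ways to split the 8 libraries into 4 and 4, 1 gave as many called genes, the real split. It gave 5369 against at most 0 in the others. A share of 1 in 35 is the smallest these splits can give. Every other split mixed the groups, so any group difference added to its spread and lowered its calls. The real split stood out as far as this design allows, which does not exclude chance for the number of genes. For the number of gene lists, 7 of the 35 splits gave as many, the real one with 8 and the highest other with 10. The other 6 of these splits each kept 3 libraries of a group together, so they carried part of the group difference. They do not measure chance alone, so the count cannot decide, and chance is not excluded for that number. Of the splits that mix the groups evenly, none gave over 7 lists.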
